A study of Mus musculus with 2 samples.

How the data were processed

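Nuclei from the spinal cords of iNeuroD1GFP mice, a transgenic line in which tamoxifen induces NeuroD1 and whose name includes GFP, were profiled by single-nucleus RNA sequencing with 10x Genomics 3′ chemistry, 10 days after injury. There were 2 libraries, 1 labelled injury core and 1 labelled distal region, and no replicate of either. The deposited matrices hold raw UMI counts per gene and barcode, with no normalisation, and per the file headers they were written by Cell Ranger 7.1.0. The submitters' notes name Cell Ranger, Seurat and the builds GRCh38 and mm10 without saying what each was used for, and the annotation is not given in the sources used here. All 32285 features carry mouse Ensembl gene identifiers, and 32158 of them (99.6%) occur in GENCODE M21 on GRCm38, from which positions were taken. The feature table names 0 GFP or Cre features, so a Neurod1 UMI was not separable into transgene and endogenous transcript. The lowest UMI total of a barcode was 500 in both libraries, so barcodes had been called or filtered before deposit.

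Barcodes with at least 300 genes and at most 5% mitochondrial UMIs were kept, which removed 2 of 16362 barcodes from the core library and 9 of 7452 from the distal library. Scrublet, run per library through scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0), called 0 doublets in both. Its thresholds of 0.608 and 0.492 lay above the highest scores of 0.556 and 0.354, so the caller was treated as not having worked, and doublets were left in. For clustering, counts were scaled to 10000 per nucleus and log-transformed after adding 1. The 2000 most variable genes, chosen without Neurod1, mitochondrial genes, Xist, Tsix and 4 Y-linked genes, gave 40 principal components. A graph of 15 neighbours with shared-neighbour weights was clustered by leidenalg 0.10.2 at resolution 1.0, both libraries together and without integration, which gave 29 clusters.

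The marker genes of 12 cell classes, 34 gene lists, the comparisons, the rule for naming genes and most alternatives were fixed before the data were examined. The rules that turn clusters into classes were set after the data had been seen. Each cluster took the class whose markers had the highest mean log2 fold over the mean of the classes, with 5 CPM added and at least 3 markers detected. Clusters were kept out of the classes on 4 grounds. In background-like clusters the nuclei varied little more than random sampling from a single shared profile would make them, by the 90th percentile over genes of the squared deviation over the expected count. In blood and mitochondrial clusters at least 3 of the 10 leading genes were haemoglobin or mitochondrial genes. Mixed clusters had more than 2 times the library's median UMIs per nucleus and more than 2 times the usual level of a second class's markers. The last ground was the lack of own markers among the 30 leading genes, which was not asked of neuron clusters.

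With 1 library per region no model across genes was fitted and no p-value is given, since nuclei are not replicates. Shares of nuclei carry exact Clopper-Pearson 95% intervals, UMI totals carry exact Poisson 95% intervals, both scaled to the total UMIs of the class as CPM, and ratios carry exact conditional 95% intervals. All intervals and floors cover counting error only, not differences between animals, dissections or libraries, and no difference between the libraries has a replicate check. A count of 0 was given the limit that 3 counts allow. Marker shares were also computed after each nucleus was thinned at random to 1000 UMIs, which left out 5181 core and 1507 distal nuclei below that depth. Beside each share of nuclei with a marker stands the share in oligodendrocytes, which should lack neuronal genes, as a measure of free RNA, and for the core library the level in background-like nuclei is given too.

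Neurod1-positive nuclei, with at least 1 UMI, were compared with negative nuclei of the same class and library in classes with at least 20 positive nuclei. Negative nuclei were weighted to the positive nuclei's distribution over 10 UMI deciles, and Neurod1 itself was left out of every sum. Core and distal libraries were compared within classes that had at least 100 nuclei in both, on summed counts. A list member counted when it had at least 10 CPM in 1 library. It was called higher or lower when its ratio reached 1.5-fold with an interval that excluded 1. List medians of log2 ratios, with 0.5 added to each count, carry intervals from 500 Poisson redraws and a percentile among 10000 random lists of the same size matched on expression. Genes were named by fixed rules. From each list at most 2 genes per direction were named, those with the largest ratios among the members called higher or lower. Over all genes, the 5 largest ratios per direction were named, among genes with at least 50 CPM and 50 UMIs in the library where they were higher and at least 0.5 times the highest class's CPM. In Neurod1-positive nuclei the genes named over all genes had at least 20 UMIs there. A few genes that these rules name are not reported here. Mitochondrial, ribosomal, sex-linked and unnamed predicted genes and the markers of other classes were left out of the naming over all genes. Hox genes other than Hoxc10, Xist and the 4 Y-linked genes, and genes of the clusters kept out of classes, were chosen after their values had been seen.

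The comparison of regions was tested on simulated data, in which 200 of the measured genes per class were changed by 2-fold or 4-fold. Intervals held the planted ratio for 95.4% of genes in neurons, 96.2% in oligodendrocytes and 96.9% in fibroblasts. Of 100 genes changed 2-fold, 99 were recovered in neurons, 72 in oligodendrocytes and 32 in fibroblasts, so smaller classes show only larger differences. Of 100 unchanged lists, 2, 1 and 4 in the same order fell outside the central 95% of random lists. The positive-against-negative comparison was tested with 100 random draws of 26 astrocyte nuclei taken as positive with no difference planted. The interval of the mature neuron list held a ratio of 1 in only 29 draws and the drawn ratios ran from 0.601 to 1.365, so intervals of list sums over so few nuclei are too narrow, because nuclei differ from each other by more than counting error. For the proneural list 80 intervals held 1 (range 0.651 to 1.564), for the immature neuron list 88 (0.782 to 1.246), for the homeostatic astrocyte list 18 (0.619 to 1.39) and for the reactive astrocyte list 68 (0.595 to 2.278). For 20 oligodendrocytes the figures were 50 for the mature neuron list (0.617 to 1.659) and 91 for the proneural list (0.44 to 1.36).

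Alternatives tried were at least 500 genes, at most 1% mitochondrial UMIs, Leiden resolutions 0.5 and 2.0, a class for each nucleus by its own marker counts, 2 Neurod1 UMIs, thinning to 500 UMIs or none, and negative nuclei not matched on depth. For the comparison of regions they were edgeR 4.0.16 TMM factors (R 4.3.3), median-of-ratios factors, means over nuclei, no minimum for list members, and subtraction of free RNA. Removal of the highest doublet scores, the background-like cluster counted as neurons, the CSF-contacting cluster left out, Anln left out of the cell cycle list and Ebf2 left out of the proneural list were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9. The Schwann repair and ependymal cilia lists gave no result, because 0 clusters were named Schwann and the ependymal class held 23 core and 18 distal nuclei. Lists for classes with fewer than 100 core nuclei are given as description only.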

Results

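Spinal cords of iNeuroD1GFP mice were injured at postnatal day 60, and the mice received tamoxifen at 100 mg/kg/day from day 5 to day 8 after injury to switch on NeuroD1, a proneural transcription factor. By the sample labels and the design text, tissue of 3 mice was collected on day 10 after injury and parted into a lesion core and a second region. The design text calls the second region distal and the extraction protocol calls it peri-injury. It is called distal here, as in the sample titles. Whether the 3 mice were pooled is not stated in the labels. Each region gave 1 library of nuclei, so no value has a replicate. The core library held 16362 barcodes and 30469264 UMIs, with 500 to 45528 UMIs per barcode and medians of 1303 UMIs and 889.5 genes over all deposited barcodes. The distal library held 7452 barcodes and 19049572 UMIs, with 500 to 69539 UMIs per barcode and medians of 1743 UMIs and 1114.5 genes. The series asks whether NeuroD1 turns glia into neurons, so Neurod1 is reported first.

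Neurod1 (ENSMUSG00000034701, GRCm38 chromosome 2, 79452521 to 79456751, minus strand) was detected at a low level in both libraries, and in the distal library its level in astrocyte, fibroblast and endothelial nuclei lay above that in oligodendrocytes and neurons. Over all barcodes it gave 122 UMIs in the core library, or 4.0 CPM (3.33 to 4.78), and 159 UMIs in the distal library, or 8.35 CPM (7.1 to 9.75), a core-over-distal ratio of 0.48 (0.38 to 0.61). At least 1 UMI was found in 0.727% of core and 2.04% of distal barcodes. Only 8 of 23803 nuclei held 2 or more Neurod1 UMIs, and 3 was the highest number in any nucleus. The counts do not separate transcripts of the transgene from those of the endogenous gene.

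Distal astrocytes held Neurod1 in 26 of 637 nuclei, or 4.08% (2.68 to 5.92), at 20.8 CPM (13.7 to 30.3). Distal oligodendrocytes held it in 20 of 1858 nuclei, or 1.08% (0.659 to 1.66), at 5.30 CPM (3.24 to 8.19), although their median depth of 1733.5 UMIs was greater than the 1446 of astrocytes. Distal neurons, at a median of 2307 UMIs, held it in 23 of 1957 nuclei, or 1.18% (0.746 to 1.76), at 4.4 CPM (2.85 to 6.50). The astrocyte level was therefore 3.93 times that of oligodendrocytes (2.12 to 7.39) and 4.73 times that of neurons (2.64 to 8.50). The neuron level was 0.83 times that of oligodendrocytes (0.44 to 1.58), a ratio at which neuronal Neurod1 reads as background. After thinning to 1000 UMIs the shares were 2.16% in astrocytes, 0.667% in oligodendrocytes and 0.328% in neurons, with 2.26% in fibroblasts. The unthinned oligodendrocyte share depended on the choice of nuclei, at 2.32% with at least 500 genes, 1.93% with the highest doublet scores removed and 1.72% when nuclei were classed one by one, and the ratio of astrocyte to oligodendrocyte CPM was then 2.86 (1.76 to 4.56), 2.97 (1.70 to 5.06) and 2.82 (1.68 to 4.64).

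Distal fibroblasts held 14 Neurod1 UMIs in 424 nuclei, or 26.4 CPM (14.4 to 44.3), 4.98 times the oligodendrocyte level (2.32 to 10.4). Endothelial nuclei were at 37.3 CPM (12.1 to 87.1) in the distal library, from 5 UMIs in 4 of 91 nuclei, and at 58.2 CPM (21.4 to 127) in the core library, from 6 UMIs in 3 of 58 nuclei, with intervals that overlap those of astrocytes and fibroblasts in the same library. Endothelial nuclei made up 3 of the 8 nuclei with 2 or more UMIs. Distal oligodendrocyte progenitors (OPCs) were near the oligodendrocyte level, at 5.83 CPM (2.14 to 12.7), and distal myeloid nuclei, at 12.2 CPM (3.97 to 28.5), did not part from it at this depth. In the core library, neurons held 76 UMIs in 8839 nuclei, 0.860% (0.678 to 1.08) unthinned and 0.321% thinned, at 3.83 CPM (3.02 to 4.8). The background-like nuclei of the core library stood at a like 4.50 CPM (2.99 to 6.51). The 308 core oligodendrocytes held 0 positive nuclei, which allows a share of up to 0.974%, and the 64 core OPCs held 0, which allows up to 4.69%. The 79 core astrocytes held 2 UMIs, 15.5 CPM (1.88 to 56.1), and core fibroblasts and core myeloid nuclei held 1 UMI each. Between the libraries, the ratio of core to distal Neurod1 was 0.87 (0.55 to 1.43) in neurons, 0.74 (0.09 to 2.96) in astrocytes and 1.56 (0.40 to 6.46) in endothelial nuclei, so no difference within these classes was detectable at this depth. The mixed clusters, kept out of the classes, held 7 core and 48 distal UMIs, a ratio of 0.27 (0.1 to 0.6).

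**Figure D1:**
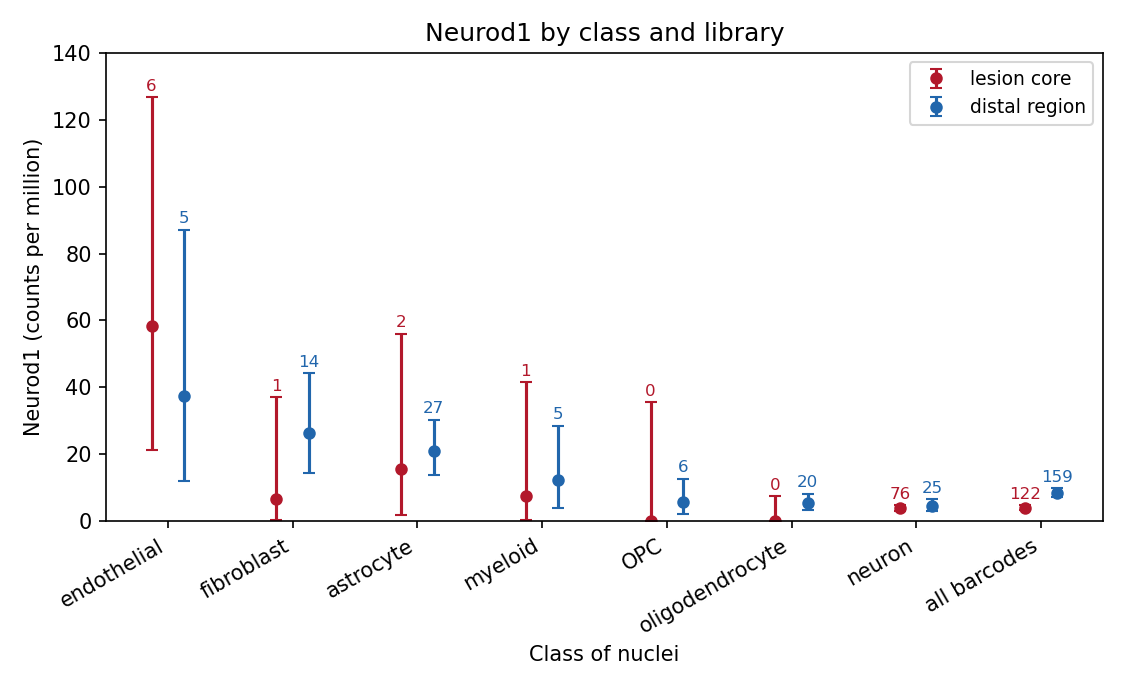
Neurod1 level in CPM by cell class in the core and distal libraries, with exact Poisson 95% intervals as bars and UMI counts written above the points. Distal astrocytes (20.8 CPM) lie above distal oligodendrocytes (5.30 CPM) and distal neurons (4.4 CPM).

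To ask whether nuclei with Neurod1 RNA carried a neuronal programme, positive nuclei were set against negative nuclei of the same class, library and depth. Most positive nuclei held only 1 Neurod1 UMI, as in distal astrocytes with 27 UMIs in 26 nuclei. At this depth a nucleus without a UMI may express the gene as well. Ratios near 1 therefore do not show that a neuronal programme was absent. In distal astrocytes (26 positive, 611 negative, median 2291.5 and 1429 UMIs) the mature neuron list, which includes Snap25, Syt1 and Rbfox3, had a ratio of 1.0 (0.934 to 1.08). The immature neuron list was lower at 0.827 (0.698 to 0.974), and Dcx, the microtubule gene of young neurons, had 1 UMI, a ratio of 0.371 (0.009 to 2.22). The list of proneural factors and early targets was higher at 1.32 (1.07 to 1.62), and at 1.76 (1.32 to 2.31) with the highest doublet scores removed. A single member, Ebf2, carried this, with 471.1 of the list's 1052.5 CPM in positive nuclei and 160.6 of 796.4 CPM in negative nuclei. Without Ebf2 the list's ratio was 0.914 (0.686 to 1.198), and 1.21 (0.827 to 1.719) with the highest doublet scores removed too. Astrocyte class markers were lower at 0.761 (0.693 to 0.835), the homeostatic astrocyte list at 0.830 (0.790 to 0.872) and the reactive astrocyte list higher at 1.34 (1.11 to 1.61), although it was 0.955 with the highest doublet scores removed. Every one of these ratios, as computed on all nuclei, lay within the range that random draws of 26 astrocytes gave with no difference present for the lists so tested, which leaves out the class markers. The proneural ratio of 1.76 lay above the highest such draw, 1.564, which was made without that removal.

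Single genes in the positive astrocytes rested on few nuclei. Ebf2, a neuronal transcription factor, was 2.93 times higher (2.07 to 4.09) from 47 UMIs, which lay in 8 of the 26 nuclei, 13 of them in a single nucleus. Dach1 was at 2.79 (1.72 to 4.37), Arpp21 at 2.35 (1.69 to 3.22) and Apoe at 2.13 (1.40 to 3.12) with 22 of 30 UMIs in a single nucleus. From the mature neuron list, Rbfox3 was at 2.10 (1.40 to 3.06). The astrocyte genes Gpc6 at 0.480 (0.336 to 0.666) and Gpc5 at 0.540 (0.439 to 0.656) were lower, as were Cdh2 at 0.539, Inpp4b at 0.566 and Shroom3 at 0.594. Among the other lists in these astrocytes, the chondroitin sulfate proteoglycan list stood at 0.748 (0.608 to 0.913) and the cell cycle list at 1.39 (1.05 to 1.81). The interval held 1 for Notch and glial fate factors (0.937), p53 (1.47), ER stress (0.774), hypoxia (0.994), immediate early (1.41), interferon (1.51), complement (1.38), cytokine (1.37) and cholesterol synthesis genes (1.11).

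In distal oligodendrocytes (20 positive, 1838 negative) the mature neuron list had a ratio of 0.862 (0.746 to 0.992), the proneural list 0.901 (0.630 to 1.25) and the immature neuron list 0.864 (0.715 to 1.04). Their class markers were at 1.10 (1.04 to 1.16) and the myelin list at 1.07 (0.996 to 1.14), and the mature neuron and class marker directions turned under 2 of the alternative ways of choosing nuclei. Arhgef2 (2.13, 1.31 to 3.28), Bcat1 (2.04), Stox2 (2.03), Gng12 (1.90) and Gbf1 (1.88) were among the highest genes, and Sgcz (0.607), Rora (0.666), Klhl2 (0.697) and Aff3 (0.706, 0.446 to 1.06) among the lowest.

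In core neurons (76 positive, 8763 negative) the mature neuron list had a ratio of 1.0 (0.974 to 1.03), the proneural list 1.02 (0.914 to 1.13) and the immature neuron list 1.07 (0.964 to 1.19). The highest genes were Zswim8 at 2.25 (1.55 to 3.15), Srsf2 at 2.21, Kat6a at 2.06, Hipk1 at 2.06 and Tmem259 at 2.01. The lowest were Vwc2 at 0.605 (0.391 to 0.895), Sez6l at 0.616, Mapre2 at 0.622, Rtn4 at 0.639 and Kif13a at 0.646. In distal neurons (23 positive, 1934 negative) the mature list was at 1.05 (0.997 to 1.10), the immature list at 1.01 (0.855 to 1.19) and the proneural list at 1.18 (1.02 to 1.37), with Elavl2 at 2.32 and Elavl4 at 1.75 but Elavl3 at 0.587. From the mature list Syt1 was at 1.84, Rbfox3 at 0.621 and Syn1 at 0.478. The excitatory list was lower in its sum at 0.639 (0.481 to 0.833), but its median log2 ratio of -0.20 lay at percentile 24.5 of random lists. The cholinergic list was higher at 2.81 (1.59 to 4.64), from 16 UMIs over the 23 positive nuclei. No random draws were made for neurons, so these intervals may be too narrow, as they were in astrocytes. The CSF-contacting neuron list was at 3.13 (2.44 to 3.95), but 39 of the 40 UMIs of its member Pkd1l2 and 59 of the 63 UMIs of Col25a1, the highest gene at 6.25, came from a single nucleus each. Without the cluster of CSF-contacting neurons that list's ratio was 0.801.

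Among named classes, the regions differed most in astrocytes, OPCs, myeloid nuclei and oligodendrocytes, which were scarce in the core library. Neurons made up 54.0% of core barcodes (53.3 to 54.8, 8839 nuclei) and 26.3% of distal barcodes (25.3 to 27.3, 1957 nuclei), a ratio of 2.06 (1.96 to 2.16). Oligodendrocytes made up 1.88% of core (1.68 to 2.10) and 24.96% of distal barcodes (24.0 to 25.96), a share 13.3 times higher in the distal library (11.7 to 15.01). Astrocytes were 0.483% of core (0.382 to 0.601, 79 nuclei) and 8.56% of distal barcodes (7.93 to 9.22), 17.7 times higher in the distal library (14.01 to 22.7). Myeloid nuclei, which include microglia and macrophages, were 0.306% of core (0.227 to 0.403, 50 nuclei) and 4.61% of distal barcodes (4.14 to 5.11), 15.1 times higher in the distal library (11.2 to 20.7). The core-over-distal ratio of myeloid shares, 0.066, was 0.028 at Leiden resolutions 0.5 and 2.0 and 0.124 when nuclei were classed one by one.

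OPCs were 0.391% and 6.17% of barcodes in core and distal, fibroblasts 0.715% and 5.70%, and endothelial nuclei 0.355% and 1.22%. Mural nuclei numbered 5 and 25 and ependymal nuclei 23 and 18. Of nuclei with a named class, neurons were 92.6% in core (92.1 to 93.1) and 33.7% in distal (32.5 to 34.9). A single background-like cluster held 37.4% of core barcodes (6116, median 934 UMIs) and 0.860% of distal barcodes. Clusters of mixed classes held 2.45% of core and 12.7% of distal barcodes, blood and mitochondrial clusters 1.84% and 7.13%, and a cluster led by liver genes 0 core barcodes, which allows up to 0.018%, and 1.25% of distal barcodes. Nuclei of a class also fell into different clusters. Of core neurons 52.97% lay in cluster 1, which held 59 distal nuclei, and the largest cluster of distal neurons, cluster 11 with 23.4% of them, held 48 core nuclei. Core oligodendrocytes lay to 87.7% in cluster 2 and distal oligodendrocytes to 55.6% in cluster 4. The core-over-distal ratio of oligodendrocyte shares, 0.075, was 0.004 at Leiden resolution 0.5, 0.002 among barcodes with at least 500 genes and 0.070 when nuclei were classed one by one. The astrocyte nuclei lay mostly in cluster 20 in core (62.0%) and cluster 13 in distal (67.3%), and OPCs in cluster 24 in core (67.2%) and cluster 17 in distal (85.8%), of which cluster 24 had 0 OPC markers among its 10 leading genes and cluster 17 had 4.

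**Figure D2:**
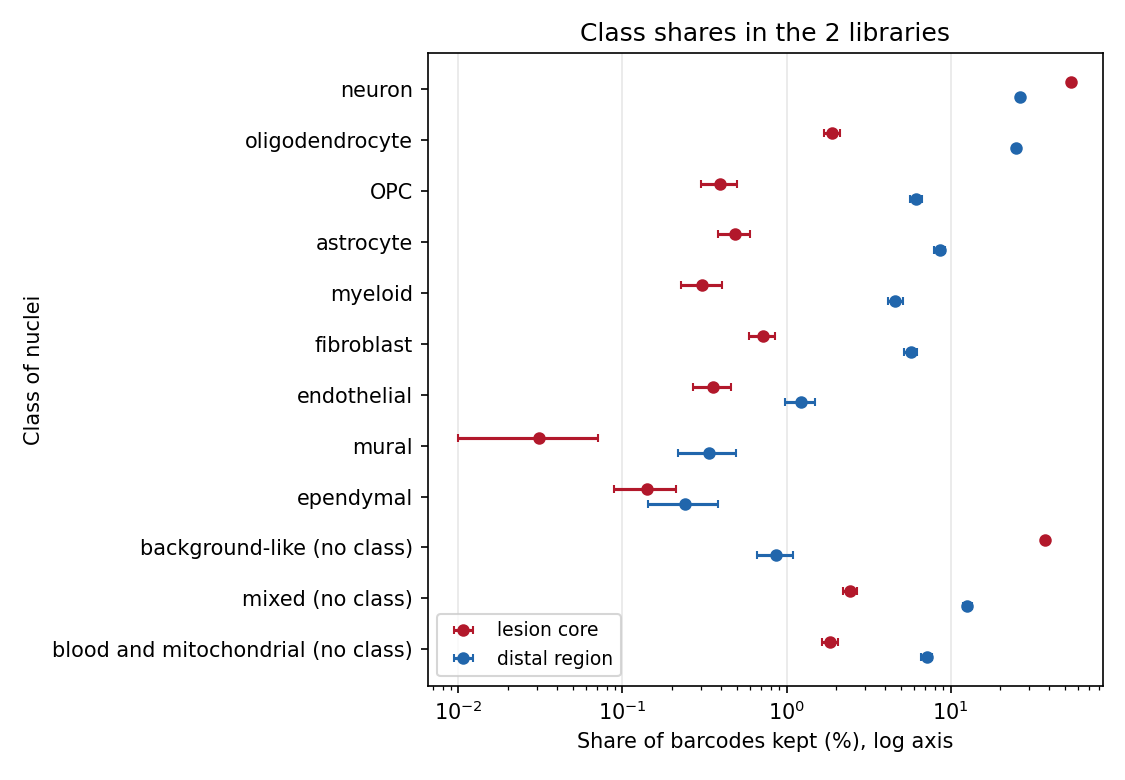
Share of barcodes in each cell class and in the clusters kept out of classes, in percent, for the core and distal libraries, with exact 95% binomial intervals as bars. Neurons were 54.0% of core barcodes against 26.3% of distal barcodes, and oligodendrocytes 1.88% against 24.96%.

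Within classes, neurons, oligodendrocytes and fibroblasts had enough nuclei for a comparison of regions. Core neurons were lower in CSF-contacting neuron genes and in part of the excitatory genes, while most members of the inhibitory and mature neuron lists were neither higher nor lower. Within neurons Hoxd11, a gene of the head-to-tail axis, had 389 core and 0 distal UMIs, so the libraries may come from different levels of the cord. Differences between core and distal neurons cannot be told apart from a difference in cord level. The excitatory list had a median log2 ratio, core over distal, of -0.58 (-0.69 to -0.32), at percentile 0.1 of random lists, with 4 of 9 members lower, 5 neither and 0 higher. Most of the difference between its sums, 695 and 1104 CPM, came from Ebf2, at 286 and 623 CPM, and the excitatory marker Slc17a6 was alike at 55.4 and 59.7 CPM. Ebf2 at a ratio of 0.460 (0.441 to 0.480) and Tac2, which encodes neurokinin B, at 0.514 (0.383 to 0.694) were the lowest. The inhibitory list had a median of 0.21 (0.08 to 0.43), inside the central 95% of random lists at percentile 89.4, with 4 of 6 members neither higher nor lower and 2 higher, Pax2 at 1.68 (1.49 to 1.91) and the glycine transporter gene Slc6a5 at 1.59 (1.39 to 1.82). The CSF-contacting list had a median of -2.72 (-2.89 to -2.53, percentile 0.0), with 4 of 4 members lower, among them Pkd2l1 at 0.104 (0.088 to 0.124) and Pkd1l2 at 0.135 (0.118 to 0.153). The cluster of these neurons held 43 of 8839 core neurons, or 0.486% (0.352 to 0.655), and 60 of 1957 distal neurons, or 3.07% (2.35 to 3.93).

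The mature neuron list had a median of 0.26 (0.20 to 0.30, percentile 99.4), with 19 of 21 members neither higher nor lower and 2 higher, Meg3 at 1.56 (1.54 to 1.57) and Slc12a5 at 1.51 (1.39 to 1.66). The proneural list (median 0.24, percentile 86.3) had 1 of 5 members lower. The immature list (-0.16, percentile 12.5) had Tubb3 higher at 1.56 (1.37 to 1.78) and 3 of 13 members lower, among them Sox4 at 0.439 (0.325 to 0.595) and Stmn1 at 0.447 (0.374 to 0.536). The cholinergic list (0.23, percentile 86.8) had 1 of 3 members higher, Hoxc10 at 12.5 (7.84 to 21.2), and its median was -0.97 with no CPM minimum. As a Hox gene, Hoxc10 also follows the head-to-tail axis, so its ratio does not by itself show a change in cholinergic neurons. The Notch and glial fate list (-0.08, percentile 45.3, but 0.046 with TMM scaling) had Sox2 lower at 0.173 (0.110 to 0.267). In the remaining lists single members were lower, Trp53inp1 of p53 genes at 0.468, Ndrg1 of hypoxia genes at 0.285 and Anln of cell cycle genes at 0.143 (0.117 to 0.175). The medians were -0.29 for the p53 list, 0.13 for the hypoxia list, -0.33 for the cell cycle list and -0.06 for the ER stress list, of which 0 of 5 members differed and whose sign turned to 0.07 with TMM scaling. Of immediate early genes 2 had enough counts, and Npas4 was higher at 2.13 (1.63 to 2.83).

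Over all genes, neurons of the core library were highest against distal neurons in Taco1 at 3.89 (3.49 to 4.35), Hjurp at 3.17 (2.68 to 3.77), Syt2 at 2.44 (2.26 to 2.65), Ints1 at 2.39 (2.07 to 2.79) and Shkbp1 at 2.34 (2.03 to 2.71). Beside the CSF-contacting genes, they were lowest in Sorbs2os at 0.368 (0.327 to 0.414), Arhgap6 at 0.439 (0.424 to 0.455) and Cpne8 at 0.459 (0.430 to 0.491). TMM scaling shifted the median of all genes by 0.13 (log2) in neurons and by -0.10 or -0.11 in oligodendrocytes with TMM or median-of-ratios factors, and median-of-ratios factors shifted it by -0.14 in fibroblasts.

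Core oligodendrocytes held less myelin RNA and more neuronal RNA than distal oligodendrocytes. The core class rested on 308 nuclei, 270 of them in cluster 2. With at least 500 genes or the highest doublet scores removed, fewer than 100 core oligodendrocytes were left. The comparison therefore gave no value under those alternatives. The myelin list had a median log2 ratio of -1.13 (-1.20 to -0.97, percentile 0.0), with 12 of 15 members lower, among them Mal at 0.238 (0.137 to 0.384) and Opalin at 0.285 (0.154 to 0.484). The disease-associated oligodendrocyte list was lower at -0.96 (-1.12 to -0.63, percentile 0.0), with 6 of 10 members lower, Il33 at 0.057 (0.001 to 0.324) from 1 against 133 UMIs and Sgk1 at 0.392 (0.258 to 0.572). The mature neuron list was higher at 1.45 (1.31 to 1.58, percentile 100.0), with 18 of 20 members higher, Syt1 at 3.37 (2.99 to 3.78) and Nefh at 3.25 (1.31 to 7.41). This rise may come from free RNA, since the list was higher in other core classes outside neurons too. An estimate from the markers of other classes put free RNA at 46.9% of UMIs in core and 33.2% in distal oligodendrocytes. With it subtracted, the myelin median was -0.60 and the disease-associated median -0.47. The estimate reached its limit of 90% in core neurons, core fibroblasts and core astrocytes, where no corrected value was computed.

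The proneural list was higher in core oligodendrocytes at 1.33 (1.04 to 1.57, percentile 99.7), with 4 of 5 members higher, Ebf3 at 3.61 (2.66 to 4.86) and Elavl2 at 2.53 (1.93 to 3.29), but Elavl2 was at 0.092 after free RNA was subtracted. The sum of this list was 1.533 times higher in core oligodendrocytes, beside 1.514 times in fibroblasts, 1.403 times in astrocytes and 1.593 times in myeloid nuclei. The rise may thus come from free RNA, and a proneural shift in oligodendrocytes is not shown. The immature neuron list (0.56, percentile 96.9) had 5 members higher, with Crmp1 at 3.88 and Stmn2 at 3.58, and 1 of 12 lower, Stmn1 at 0.631. The differentiating oligodendrocyte list (-0.42, percentile 1.3) had 5 of 11 members lower, with Sox10 at 0.291 (0.165 to 0.479) and 9630013A20Rik at 0.284. The cholesterol synthesis list (-0.52, percentile 0.1) had 3 of 17 lower, with Sqle at 0.326 (0.129 to 0.687) and Idi1 at 0.143 (0.004 to 0.834) from 1 against 53 UMIs. The cell cycle list (-0.82, percentile 0.7) had Ezh2 at 0.550 and Anln at 0.566, and the Notch list (-0.38, percentile 13.6, but 0.055 with free RNA subtracted) had Nfia at 0.546. The hypoxia list (0.28, percentile 72.1) had Pfkp at 3.25 and Slc2a1 at 0.310, 0 of 6 members differed in the p53 list (-0.35) and in the ER stress list (-0.33), and Npas4 was at 4.05 (1.49 to 10.2). The largest ratios over all genes belonged to neuronal genes, Sv2c at 5.91 (4.18 to 8.31), Glra1 at 5.30 (3.94 to 7.1), Kcnd3 at 4.76, Tafa1 at 4.39 and Lrrtm4 at 4.15 (3.83 to 4.50), which may come from free RNA too. The smallest were those of Npsr1 at 0.071 (0.009 to 0.259), Dnajc19 at 0.166, Ppp1cc at 0.172, Grm3 at 0.175 (0.138 to 0.219) and Dapk2 at 0.177.

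Core fibroblast barcodes held more neuronal RNA than distal ones, and the summed CPM of their scar matrix genes was 0.832 times the distal sum (0.717 to 0.961). The higher neuronal lists cannot be told from free RNA, estimated at its limit of 90% of UMIs in core and at 86.2% in distal fibroblasts. Free RNA may bear on the lower matrix sum as well, which was not tested. The mature neuron sum was 2.352 times higher in core fibroblasts, beside 2.846 times in oligodendrocytes, 2.49 times in astrocytes and 2.176 times in myeloid nuclei. The fibrotic matrix list, which includes the collagens, had a median of -0.21 (-0.62 to 0.07, percentile 19.8), with 12 of 15 members neither higher nor lower and 3 lower. Of these, Sparc was at 0.321 (0.084 to 0.882), and Tnc had 0 core against 15 distal UMIs. The mature neuron list was higher at 1.10 (0.92 to 1.29, percentile 100.0), with 16 of 20 members higher, the largest Nefh at 5.89 (5 against 3 UMIs) and Nefm at 4.12 (7 against 6 UMIs), although both ratios lay below 1 when nuclei were classed one by one. The proneural list (0.81, percentile 98.0) had 3 of 5 members higher, with Elavl4 at 3.83 and Elavl2 at 1.86. The immature list (0.41, percentile 94.4) had Crmp1 at 4.24 and Dcx at 3.06 (1.34 to 6.90) higher and Nnat at 0.416 lower.

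The Notch and glial fate list was lower in core fibroblasts (-0.65, percentile 2.2), with 3 of 9 members lower, among them Nfib at 0.597 (0.434 to 0.805) and Id3 with 0 against 15 UMIs. The cell cycle list (-2.29, percentile 0.0) had Anln at 0.079 (0.009 to 0.295) and Ezh2 at 0.202 (0.024 to 0.786) lower, from 2 core UMIs each, out of 4 members. Anln was at 168 CPM in distal fibroblasts but 573 CPM in distal oligodendrocytes, and was lower in core neurons too, at 7.4 against 51.8 CPM. With free RNA estimated at 86.2% of UMIs in distal fibroblasts, the difference of Anln there may come from free RNA, which was not tested. The same holds for the lower members of the Notch and glial fate list and of the hypoxia list. The hypoxia list (-0.78, percentile 1.3) had Pfkp at 2.08 higher and Ndrg1 at 0.050 (0.001 to 0.291) lower. In the p53 (-0.42), ER stress (-0.02) and immediate early lists (0.46) 0 of 9, 7 and 6 members differed. The largest ratios were those of the neuronal genes Chrm3 at 4.16 (2.74 to 6.33), Kcnip1 at 3.97, Cntnap5b at 3.84, Sptbn4 at 3.72 and Nkain3 at 3.66, which likewise cannot be told from free RNA. The smallest were Ccp110 at 0.053, Tsc22d3 at 0.065 and Josd2 at 0.067, with 1 core UMI each, Scd2 at 0.105 (0.028 to 0.274) and Gatm at 0.122 (0.025 to 0.368).

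**Figure D3:**
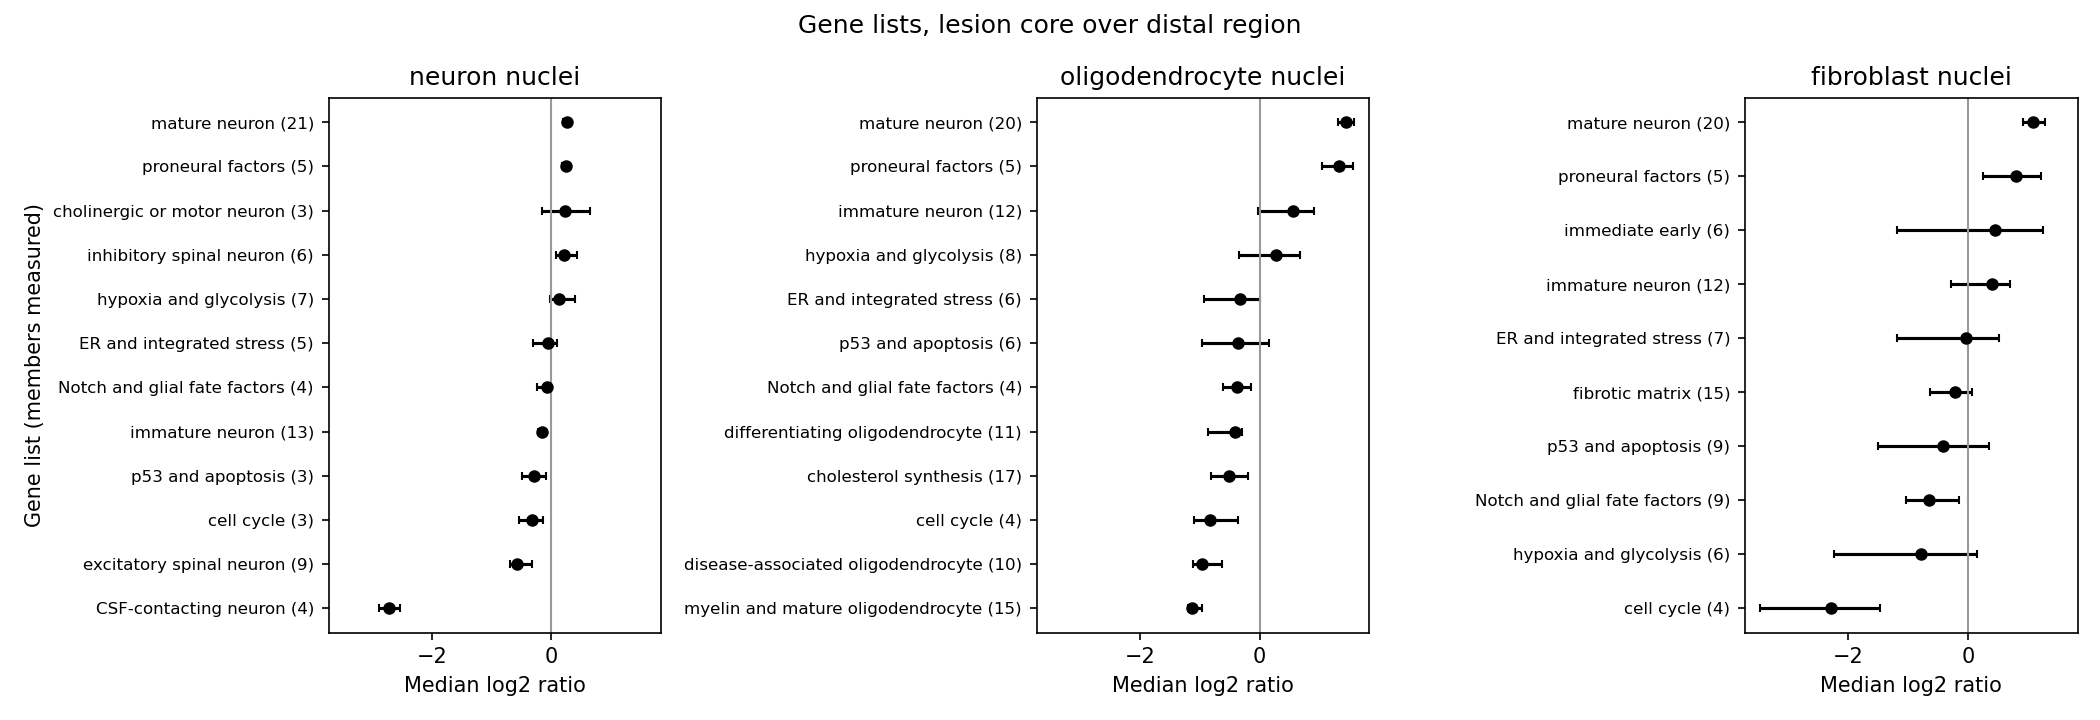
Median log2 ratio, core over distal, of each gene list in neurons, oligodendrocytes and fibroblasts, with 95% counting intervals as bars. The mature neuron list lay above 0 in all 3 classes, at 0.26, 1.45 and 1.10 in the same order, and the myelin list lay at -1.13 in oligodendrocytes.

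Neuronal subtypes and immature neurons were looked for in each region. At 1000 UMIs, 14.5% of core neurons (13.7 to 15.3) held a UMI of Gad1, Gad2, Slc6a5 or Slc32a1, the inhibitory markers, against 9.14% of distal neurons (7.86 to 10.6). In oligodendrocytes, which should lack them, the shares were 7.09% in core (4.25 to 10.97) and 3.27% in distal. The core background-like nuclei, however, were at 15.6% (14.1 to 17.3), so the core share is not shown to lie above free RNA. The excitatory marker Slc17a6 was found in 5.93% of core neurons (5.42 to 6.46) and 6.29% of distal neurons (5.22 to 7.51), beside 3.54% (1.63 to 6.62) and 0.788% of oligodendrocytes. The core Slc17a6 share lay within the interval of core oligodendrocytes, but over all UMIs core neurons were higher, at 55.4 CPM (52.2 to 58.8) against 28.2 CPM (15.4 to 47.3), while background-like nuclei were at 61.6 CPM (55.6 to 68.1). Cholinergic markers Chat or Slc5a7 were found in 0.555% and 0.493% of core and distal neurons, and in 0.394% and 0.424% of oligodendrocytes. Over all UMIs distal neurons stood at 14.8 CPM (11.8 to 18.3), with 13 nuclei of 2 or more such UMIs and up to 12 in a nucleus, above distal oligodendrocytes at 3.71 CPM (2.03 to 6.23) with 0 such nuclei. Core neurons, at 6.35 CPM (5.29 to 7.57), did not part from the core background-like nuclei at 8.36 CPM (6.24 to 10.96). Dcx was found in 5.86% of core neurons (5.36 to 6.40) and 6.73% of distal neurons (5.63 to 7.98), beside 3.94% (1.90 to 7.12) and 1.27% of oligodendrocytes, so the core Dcx share too lay within the interval of core oligodendrocytes. Over all UMIs core neurons were at 59.3 CPM (55.97 to 62.8), above core oligodendrocytes at 34.2 CPM (19.9 to 54.8) but not above background-like nuclei at 68.7 CPM (62.3 to 75.5). Unthinned, the shares in core and distal neurons were 25.9% and 20.2% for inhibitory markers, 10.7% and 14.1% for Slc17a6, 1.10% and 2.10% for cholinergic markers and 11.9% and 16.1% for Dcx. Thinning left out 738 core and 130 distal neurons. Median depths were 1867 and 2307 UMIs in core and distal neurons, and 1434.5 and 1733.5 UMIs in oligodendrocytes.

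Cell cycle genes were compared to look for proliferation in classes with at least 100 nuclei in both libraries. At 1000 UMIs, at least 2 UMIs of the cell cycle list were found in 11.02% of core oligodendrocytes (7.45 to 15.5) and 16.4% of distal oligodendrocytes (14.7 to 18.3). Most of this came from Anln, which myelinating oligodendrocytes also express, with 70.0% and 75.8% of the list's UMIs. Without Anln the shares were 0.394% and 1.58%. Neurons were at 0.988% in core (0.784 to 1.23) and 1.97% in distal (1.38 to 2.72), the latter 0.930% without Anln. Of fibroblasts 0 of 52 core nuclei passed, which allows a share of up to 5.77%, and 5.43% of 221 distal nuclei (2.84 to 9.29) did. Anln made up 43.4% of the list's UMIs in distal fibroblasts, and without it the distal share was 2.715% (1.003 to 5.815). Unthinned shares were 18.8% and 39.8% in oligodendrocytes, 4.70% and 12.4% in neurons and 0.855% and 8.26% in fibroblasts, core first. Mki67 and Top2a, which mark dividing cells, together gave 2.01 and 3.71 CPM in core and distal oligodendrocytes, 1.36 and 2.99 CPM in neurons. In fibroblasts they gave 0 core UMIs, which allows up to 19.97 CPM, and 11.3 CPM (4.15 to 24.6) in distal, a difference not detectable at this depth. No cycling was read from these shares in neurons or oligodendrocytes.

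The libraries also differed in genes that mark the sex of animals and the level of the cord. Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254, minus strand), expressed from the inactive X chromosome of females, gave 16 UMIs in the core library, or 0.53 CPM (0.30 to 0.85), and 14776 UMIs in the distal library, or 775.9 CPM (763 to 789), in 57.2% of distal nuclei. Both libraries were labelled male. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y together gave 270.6 CPM in core and 194.6 CPM in distal. Among Hox genes, whose expression follows the head-to-tail axis, those of groups 10 and 11 differed most. Hoxc10 (ENSMUSG00000022484, chromosome 15, 102966796 to 102971893, plus strand) was 14.4 times higher in core (10.8 to 19.7, 1084 against 47 UMIs). Hoxa10 was 11.2 times higher (7.38 to 17.9), and Hoxd10 had 199 against 1 UMI, a ratio of 124 (22.1 to 4937). Hoxd11 (ENSMUSG00000042499, chromosome 2, 74679557 to 74687016, plus strand) had 598 core and 0 distal UMIs, at least 124.6-fold higher against the floor of 3 counts over the distal library, and Hoxc11 had 78 and 0, at least 16.3-fold higher. Outside these groups Hoxd9 (3.75), Hoxc5 (3.65), Hoxc8 (3.26), Hoxc9 (2.86), Hoxc4 (2.73) and Hoxd3 (2.38) were also higher in core, and within neurons at 7.35, 2.25, 2.05, 1.90, 1.76 and 1.88 in the same order, the first from 77 against 3 UMIs. Hoxd8 was lower in core at 0.625 (0.472 to 0.827), and at 0.595 (0.366 to 0.989) within neurons. Hoxa9 (1.38), Hoxb8 (1.33) and Hoxc6 (1.35) differed less, and within neurons their ratios were 0.815 (0.699 to 0.952), 0.943 (0.796 to 1.122) and 0.856 (0.777 to 0.944), so that direction turned for Hoxa9 and Hoxc6.

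**Figure D4:**
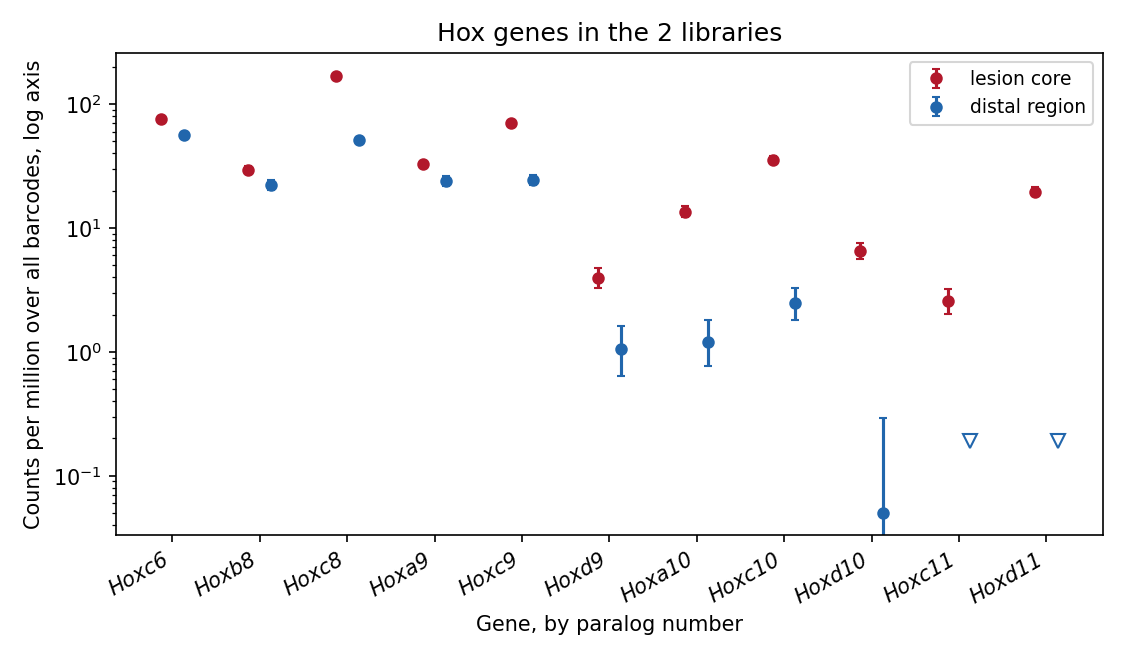
CPM of Hox genes over all barcodes of the core and distal libraries on a log axis, with exact Poisson 95% intervals as bars and open triangles at the floor of 3 counts for genes with 0 UMIs. Hoxc10 (1084 against 47 UMIs) and Hoxd11 (598 against 0 UMIs) lay far higher in the core library.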

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

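All tests of explanations in this part were chosen only after the result was seen.

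Xist reached 775.9 CPM in the distal library and 0.53 CPM in the core library, although both were labelled male, and it stood out because it lies outside the planned comparisons. Free Xist RNA or doublets among male nuclei are argued against, since distal nuclei with 2 or more Xist UMIs held Y-linked UMIs 0.549 times as often as nuclei with none at equal depth (0.454 to 0.660), and rarer Y-linked UMIs in Xist-positive nuclei were seen within neurons (6.88% against 16.3%), oligodendrocytes (12.8% against 23.2%) and astrocytes (10.6% against 23.0%). An all-female distal library is argued against by Y-linked CPM at 0.719 times the core level (0.691 to 0.747). Nuclei of both sexes in the distal library remain open as a candidate explanation, with Y-linked CPM in distal oligodendrocytes at 0.691 times the core level (0.588 to 0.816), between the values of an all-male and an all-female library. The labels name no sex as a group, so no biological explanation was tested. If the distal library holds female nuclei, the core library, with 16 Xist UMIs, holds few or none of them. The animals behind the 2 libraries would then differ, and part of any difference between the libraries may come from that.

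Hoxd11 had 598 UMIs in the core library and 0 in the distal library, a signal outside the planned gene lists. A cluster of 93 distal barcodes, with a median of 755 UMIs and 0 core barcodes, was led by liver genes, with Apoa1 at 2241 CPM, Apoa2 at 2043 CPM and Alb at 1878 CPM. A cluster of 533 distal and 3 core barcodes, with a median of 3662 UMIs in the distal library, held both the myelin transcript Mbp at 2527 CPM and the myeloid transcript Csf1r at 80.9 CPM, with 38 Neurod1 UMIs.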

How the results depend on the processing

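Tests with the highest doublet scores removed, the background-like cluster counted as neurons, the CSF-contacting cluster left out and Anln or Ebf2 left out were chosen only after the result was seen, and the others were planned. No paired analysis was possible because each region had a single library. Where a cause is not named, the cause was not tested.

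In the comparison of regions within classes, 48 of the 53 leading values that could be computed stayed within the interval of the value reported, as did 268 of 310 others and 771 of 847 values of 81 named genes. For class shares these were 20 of 32 and 95 of 136, for Neurod1 detection 27 of 42 and 23 of 32, for positive against negative nuclei 7 of 12 and 100 of 128, for neuronal markers 19 of 24 and 20 of 24, and for the cell cycle 11 of 27 and 10 of 14. The neuron share was higher in core, and the oligodendrocyte, astrocyte and myeloid shares lower, under every alternative that gave a value. Distal astrocytes kept more Neurod1 CPM than distal oligodendrocytes and neurons under all 5 alternatives run, 2.82 to 4.03 and 3.59 to 5.2 times.

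Counting fewer UMIs lowers shares by construction. Requiring 2 Neurod1 UMIs gave 0.157% of distal astrocytes, 0.0% of distal oligodendrocytes, 0.102% of distal neurons and 0.0% of core neurons. Thinning to 1000 UMIs gave 2.16% of distal astrocytes, 0.328% of distal neurons and 0.321% of core neurons, and thinning to 500 gave 1.73%, 0.255% and 0.192%, with 0.323% of distal oligodendrocytes. At 500 UMIs, excitatory markers were in 3.11% and 3.02% of core and distal neurons, inhibitory markers in 7.69% and 4.29%, and 2 cell cycle UMIs in 0.351% and 0.766% of neurons and 2.92% and 6.14% of oligodendrocytes. With 1 cell cycle UMI the shares were 12.8% and 19.2% of neurons and 35.0% and 50.8% of oligodendrocytes. Unthinned, the shares with 2 such UMIs were 4.70% and 12.4% of neurons and 18.8% and 39.8% of oligodendrocytes. Thinned and without Anln they were 0.930% of distal neurons and 0.394% and 1.58% of oligodendrocytes.

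At Leiden resolution 0.5 the core-over-distal share ratio was 1.45 for neurons, 0.004 for oligodendrocytes and 0.028 for myeloid nuclei, and at 2.0 it was 0.028 for myeloid nuclei. With at least 500 genes it was 1.62 for neurons and 0.002 for oligodendrocytes, and 2.32% of distal oligodendrocytes were Neurod1-positive. With at most 1% mitochondrial UMIs it was 1.47 and 0.003. With the background-like cluster counted as neurons it was 3.37 for neurons.

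Removing the highest doublet scores, 2141 core and 443 distal barcodes, gave share ratios of 1.64 for neurons and 0.004 for oligodendrocytes, Neurod1 in 1.93% of distal oligodendrocytes and 2 cell cycle UMIs in 1.29% of core neurons. In Neurod1-positive astrocytes it gave 1.12 for the mature neuron list, 1.76 for the proneural list and, reversed, 0.955 for the reactive list. Leaving Ebf2 out of the proneural list reversed it to 0.914, and both together gave 1.21. In positive oligodendrocytes the mature neuron list reversed to 1.33 and the class markers to 0.757.

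Classing each nucleus by its own markers gave 0.124 for the myeloid share ratio, Neurod1 in 1.72% of distal oligodendrocytes and 0.669% of core neurons, inhibitory markers in 13.7% of core neurons, 0.825 for the mature neuron list in positive astrocytes and a myelin median of -0.94. It reversed the mature neuron list (1.26) and the class markers (0.916) in positive oligodendrocytes, the CSF-contacting list in positive distal neurons (0.531), and Nefh (0.772) and Nefm (0.809) in fibroblasts. Leaving out the CSF-contacting cluster also reversed that list, to 0.801. Negative nuclei not matched on depth gave 1.10 for the mature neuron list in astrocytes.

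Scaling by TMM factors gave a myelin median of -1.24 and turned the Notch and glial fate list of neurons to 0.046, and median-of-ratios factors gave a myelin median of -1.24. Subtracting free RNA gave -0.60 for the myelin list and -0.47 for the disease-associated list, and reversed the Notch and glial fate list of oligodendrocytes to 0.055 and Elavl2 to 0.092, from 0.2 core UMIs left.

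Some alternatives gave no value. Oligodendrocytes had fewer than 100 core nuclei with at least 500 genes or with high doublet scores removed. Free RNA reached its 90% limit in core neurons, fibroblasts and astrocytes. Too few nuclei held 2 Neurod1 UMIs for a comparison of positive nuclei. Keeping doublets gave the same values, since none were called. Depth limits the classes with few core nuclei most, where a single UMI often decides a ratio.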

Other observations

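All tests of explanations in this part were chosen only after the result was seen, while the lists and the Neurod1 levels by class were planned.

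Classes with fewer than 100 core nuclei are described here by their list sums, core first. The 50 core myeloid nuclei held less microglial RNA than the 343 distal ones, with the homeostatic microglia list at 657 and 3029 CPM and 9 of 12 members lower, the complement list at 127 and 597 CPM with 6 of 8 members lower, and the infiltrating macrophage list at 97.1 and 369 CPM with 4 of 8 lower. Part of this may come from free RNA, estimated at 77.9% of UMIs in core and 66.7% in distal myeloid nuclei. The cholesterol efflux list was at 269 and 692 CPM with 3 of 10 members lower, and the phagocytic or lipid-associated list at 463 and 721 CPM with 2 lower and 1 higher of 14. The interferon list (119.5 and 181 CPM) and the antigen presentation list (74.7 and 171 CPM) had 0 members called, and the cytokine list had only 2 members with enough counts. In astrocytes the reactive list was at 792 and 1172 CPM and the homeostatic list at 29464 and 21690 CPM, but the estimate of free RNA reached its limit of 90% in core astrocytes, so how far these sums are free RNA is not known. The chondroitin sulfate proteoglycan list was at 1755 and 1512 CPM in astrocytes. In distal OPCs, 10.2% of nuclei (7.35 to 13.6) held 2 or more cell cycle UMIs at 1000 UMIs, and Mki67 and Top2a stood at 11.7 CPM (6.03 to 20.4), against 8.84% (6.42 to 11.8) and 3.09 CPM (0.84 to 7.91) in distal astrocytes, with Anln at 32.5% and 41.9% of the list's UMIs. Other list sums of OPCs are not set side by side, since most core OPCs lay in a cluster with 0 OPC markers among its 10 leading genes. The blood-brain barrier list of endothelial nuclei was at 9510 and 7237 CPM with 5 of 14 members higher, which may come from free RNA, estimated at 60.6% and 69.9% of their UMIs, beside 776 and 889 CPM for the angiogenic list. The mature neuron list was higher in each of these core classes, 2.49 times in astrocytes, 2.18 times in myeloid nuclei and 2.04 times in endothelial nuclei.

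Oligodendrocytes, astrocytes and OPCs numbered 5.10 per 100 neurons in the core library and 150.95 in the distal library. Without the background-like cluster and the largest core neuron cluster the core ratio was still 0.070 times the distal ratio (0.062 to 0.078). Droplets of free neuronal RNA in those clusters are therefore not the whole cause. Leaving them out took away 4682 of 8839 core neurons, too few to bring the core ratio near the distal one whatever those barcodes were. Droplets in the other core neuron clusters were not tested, so free neuronal RNA counted as neurons is not excluded. A fall in RNA shared by all core oligodendrocytes, which took most of them under the UMI minimum, is argued against, since 17.532% of core oligodendrocytes (13.5 to 22.2) were under 1000 UMIs, while distal oligodendrocytes scaled down by 1 factor until only 13.5% of them stayed above the minimum would have 85.3% (80.3 to 89.4). The 308 core oligodendrocytes would be that 13.5% if their share had been 0.5 times the distal share before such a loss. Loss of only some core glia, with too little RNA to be deposited, stays open, since barcodes under 500 UMIs are not in the files. An exchange of the library labels cannot be told apart from the labels as given. Myeloid and fibroblast nuclei, which gather in a lesion, were together 1.192 times as frequent in core among named nuclei other than neurons (1.002 to 1.411). Among all barcodes they were 0.099 times as frequent (0.083 to 0.117). On the first measure fibroblasts were at 1.511 (1.221 to 1.858) but myeloid nuclei at 0.798 (0.581 to 1.076), and on the second myeloid nuclei were at 0.066. Myeloid nuclei were thus not shown to be more frequent in core by either measure. A difference between the regions, such as loss of glia in a lesion core, stays open and was not tested.

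Neurod1 was higher in distal astrocytes than in distal oligodendrocytes and neurons. Free Neurod1 RNA is argued against, since the astrocyte level was 2.497 times that over all distal barcodes (1.60 to 3.77), and the mature neuron list, which free RNA would raise in the same ratio, was 1.78 times higher in astrocytes than in oligodendrocytes against 3.93 times for Neurod1. The second contrast was not kept under every alternative. The interval of the Neurod1 ratio held 1.78 with at least 500 genes, with the highest doublet scores removed, or with nuclei classed one by one. Free RNA was estimated at 61.9% of UMIs in distal astrocytes, 86.2% in fibroblasts and 69.9% in endothelial nuclei, against 33.2% in oligodendrocytes, with the sum over the library's barcodes taken as its source, so the test holds as far as free RNA resembles that sum. Deep nuclei are argued against, since among nuclei under 2000 UMIs the astrocyte level was 5.275 times that of oligodendrocytes and neurons together (2.25 to 12.4). This rests on 13 UMIs in astrocytes and 13 in oligodendrocytes and neurons. The cut does not remove doublets, since distal astrocytes had a median of only 1446 UMIs, so it cannot decide on them. What stays open beside doublets is expression in astrocytes of the transgene or of the endogenous gene, which the counts do not separate. The few positive fibroblast and endothelial nuclei mean that a source confined to astrocytes is not shown.

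In core background-like nuclei, UMIs of excitatory and inhibitory markers met in the same nucleus 0.940 times as often as independence would give (0.710 to 1.22), against 0.698 (0.580 to 0.832) in the largest core neuron cluster, 0.659 (0.516 to 0.830) in other core neurons and 0.442 (0.298 to 0.631) in distal neurons.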
